A study of Mus musculus with 25 samples.

How the data were processed

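Poly-A RNA was sequenced from leukocytes sorted out of injured mouse muscle and from cultured bone marrow-derived macrophages (BMDM). Per the labels' protocols, libraries were made with a TruSeq kit and sequenced on an Illumina HiSeq. Per the submitters' processing notes, TopHat2 2.0.7, DESeq and the mouse build mm10 were used, with no parameters and no statement of which tool did which step. The gene annotation behind the counts is not given in the sources used here. The kit as described marks no strand, so values of overlapping or antisense genes and of close paralogs are uncertain.

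The 2 deposited tables give log2 values: the authors took log2 of normalised read counts per gene, with values under 1 normalised count set to 0. The BMDM table has 1 column per library, 6 in all. In the muscle table each of the 5 columns is a group, and the most common low values sit at the steps that a mean of log2 values over 3 or 2 libraries gives, so the authors averaged log2 values over the samples of a group. This unit was read from the values and differs from the counts divided by size factors that had been assumed before the data were examined. Each table lists 38087 genes by Ensembl identifier and symbol. Of these identifiers 36308 (95.3%) are in GENCODE M21, which supplied coordinates on GRCm38/mm10, and 4145 genes share a symbol with another gene. In the muscle file a date stands in place of a value in 2 cells, Zcchc11 in Ly6Chigh cells at day 4 and Gpr34 in Ly6Clow cells at day 4, and both were treated as missing. No column (0) belonged to a sample outside the series.

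Samples were grouped by their labels, which give 25 samples in 9 groups. The 2 groups without a column, Ly6Chigh macrophages at day 1 and blood monocytes, with 6 samples, were not analysed here, so 3 planned comparisons with them were not run. The labels give separate samples, but nothing in them says that these are separate animals or cultures, so p-values measure the spread between samples. The most common low values of each BMDM library gave a step that was taken as 1 read, and 43.1 to 57.4% of the low values lie within 0.02 of a multiple of it. The step gives an estimate of 9.05 to 14.3 M (mega) gene reads per library. Reads without molecular identifiers are not independent molecules, so the depth describes counting error alone. For the muscle groups the depth is unknown, since the values are means.

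BMDM libraries were compared with limma 3.58.1 in R 4.3.3, on the log2 values as deposited. Genes with a mean normalised count of at least 10 were tested with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over lists, and again with an estimated correlation. Members were also counted with p-values adjusted over the list alone. In the muscle table no replicate values exist, so no test, error or paired comparison was possible there. For each pair of groups the normalised counts were recovered from the log2 values, 10 was added, and the log2 ratio was taken. The term called is used for a gene that differed at least 2-fold on that scale with the higher group at 50 or more. The fold values given for muscle are on that scale, so they are compressed for genes with low values, and none is given against a group listed at 0. For each list the median log2 ratio was placed among 10000 random lists of genes matched for level in 20 bins, and lists below percentile 2.5 or above 97.5 are described as outside the range of random lists. The difference of subset ratios between days was computed as day 4 minus day 2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.

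The 31 gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and most of the alternative settings. The 22 pathway lists were arachidonate release and platelet-activating factor (PAF), prostaglandin and thromboxane synthesis, lipoxygenase and leukotriene pathway, lipid mediator receptors, inflammatory cytokines and chemokines, repair-associated macrophage genes, monocyte genes, mature macrophage genes, MHC class II presentation, interferon response, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, cholesterol efflux and lipid handling, cholesterol biosynthesis, phagocytosis and efferocytosis, lysosome, matrix and protease genes, iron and heme handling, immediate early genes, NF-kB target genes, and cAMP and CREB target genes. The 9 marker lists were for neutrophils, T and NK cells, B cells, eosinophils and mast cells, dendritic cells, skeletal muscle and myoblasts, fibroblasts, endothelial cells, and erythroid cells and platelets. Some genes are in more than 1 list.

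Genes were named by a rule. Alox5, Alox15, Ptgs1, Ptgs2 and Gpr18 were always reported, and in muscle also the sort markers Ly6c1, Ly6c2, Emr1 (F4/80) and Ly6g. Added to these were the 8 called genes with the largest ratio in each direction, with the higher group at 100 or more in BMDM and at 200 or more in muscle. In BMDM their groups could not overlap, and unnamed gene models, antigen receptor segments, mitochondrial genes and sex-linked genes were left out. From each list up to 4 called members with the largest change and a higher group of at least 50 were taken. Symbols are those of the tables, some of them older names (Emr1 for Adgre1, Sepp1 for Selenop, Chi3l3 for Chil3, Siglec5 for Siglecf, Irg1 for Acod1, Il1f9 for Il36g).

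The alternatives tried for BMDM were a pseudocount of 0.5 or 5, no filter, a filter of 50, each library rescaled to a median log2 ratio of 0 or to equal totals, limma without the trend, the replicate number as a block, each library left out in turn, an added 1.5-fold limit, and an unadjusted p of 0.01. For muscle they were pseudocounts of 0.5, 1, 5 and 50, filters, both rescalings, and limits of 1.5-fold and 4-fold. A pseudocount of 1 in BMDM and the removal of each library's trend with GC content and length were added after seeing the data. The BMDM comparison was tested on simulated data in which 200 genes were set to change, with 15220 genes passing the filter. At log2 changes of 0.58, 1 and 2 it recovered 77.4%, 95.5% and 98.5% of the changed genes tested, and 12 of its 190 calls (6.32%) were unchanged genes. The simulation gave every gene the same dispersion (0.0024), the median of genes with high counts in the controls. It held no differences between cell preparations, so these rates do not describe genes or libraries that vary more. Muscle lists of 10, 20 and 35 genes were simulated for the subsets at day 2 only. There 4.5%, 4% and 5.5% of unchanged lists fell outside the middle range, and 77%, 97% and 100% of lists raised by 0.5 lay above it. These rates do not carry over to the neutrophil comparison. For the 10 measured arachidonate genes the random range was -1.09 to 1.28 there, against -0.39 to 0.32 between subsets at day 2. The simulated lists and the random lists were both drawn gene by gene from the same genes. They do not cover lists whose genes vary together, so the percentiles of real lists carry no error rate.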

Results

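RNA sequencing was used to measure gene expression in myeloid cells of injured mouse muscle and in cultured macrophages given resolvin D2 (RvD2), a lipid mediator made from docosahexaenoic acid. The tibialis anterior of C57BL/6J mice was injured with cardiotoxin, a snake venom toxin that kills muscle fibres. CD45+ leukocytes were taken out magnetically and sorted by flow cytometry into Ly6Chigh F4/80low macrophages (3 samples at day 2, 2 at day 4), Ly6Clow F4/80high macrophages (3 at day 2, 2 at day 4) and Ly6Ghigh neutrophils (3 at day 1). The values of each of these 5 groups were the authors' group means, so muscle differences are given without error or test and could not be set against the spread between replicates. Summed normalised counts were 11.9 to 12.8 M (mega) in the 4 macrophage groups and 26.0 M in neutrophils. BMDM were compared as 3 untreated libraries against 3 libraries of cells given 10 nM RvD2 for 4 h. Their estimated depths were 10.1, 14.3 and 9.05 M gene reads in the controls and 9.12, 9.78 and 11.9 M with RvD2. Samples of Ly6Chigh cells at day 1 (3) and blood monocytes (3) were not analysed here.

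The first question was how the 2 macrophage subsets differed at day 2, early in the transition from Ly6Chigh to Ly6Clow cells that the study title names. Ly6Clow cells had higher transcripts of cell division, lysosomes and engulfment, and lower transcripts of monocytes, antigen presentation, interferon response and inflammation. Igf1, a growth factor for muscle, was 9.62-fold higher in Ly6Clow cells (log2 ratio 3.27), and Spp1 (osteopontin) was 6.13-fold higher. Il1b, which encodes interleukin-1 beta, was 11.4-fold lower in Ly6Clow cells, and the matrix proteoglycan gene Vcan was 66.8-fold lower. Of 11275 genes with a level of 50 or more in either subset, 1281 differed at least 2-fold, 665 of them higher and 616 lower in Ly6Clow cells.

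The largest ratios toward Ly6Clow cells at day 2 were those of Htr2b (10.6-fold, log2 ratio 3.40), Adcy3 (log2 ratio 3.40), Npl (9.88-fold), Cd5l (9.66-fold), Igf1, Cspg4 (9.55-fold), Mfge8 (9.31-fold) and Atp6v0d2 (9.10-fold). Mfge8 bridges dying cells to phagocytes and Atp6v0d2 encodes a subunit of the lysosomal proton pump. Among the largest toward Ly6Chigh cells were Vcan, Plac8 (60.1-fold), Dmkn (25.9-fold), Ifitm6 (24.9-fold) and Emr4 (16.9-fold). The sorted antigen genes served as a check of the gates. Ly6c2 was 25.0-fold and Ly6c1 19.2-fold lower in Ly6Clow cells, Emr1 was at log2 levels of 13.08 in Ly6Chigh and 13.80 in Ly6Clow cells, and Ly6g was listed at 0 in both.

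Among cell cycle genes 28 of 35 measured were called higher and 1 lower in Ly6Clow cells at day 2, with a median log2 ratio of 1.97, at percentile 100 of matched random lists. Top2a, a topoisomerase of dividing cells, was 8.38-fold and Birc5 8.12-fold higher. In the mature macrophage list 10 of 16 genes were higher and 0 lower (median 1.22, percentile 100), with Lyve1 8.45-fold, Folr2 6.04-fold and the complement gene C1qa 2.97-fold higher. Lysosome genes had 7 of 24 higher and 0 lower (median 0.68), among them the protease gene Ctsd at 3.63-fold. Phagocytosis genes had 8 of 20 higher and 1 lower (median 0.29), with Gas6, a bridging ligand, 5.92-fold higher. Repair-associated genes had 7 of 19 higher and 3 lower (median 0.54), and cholesterol efflux and lipid handling genes had 6 of 22 higher and 1 lower (median 0.44), with Lpl 5.77-fold and Cd36 4.24-fold higher. Iron and heme genes (3 higher and 1 lower of 18, median 0.38) and oxidative phosphorylation genes (0 of 26 called, median 0.22) also lay above the range of random lists.

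Lists toward Ly6Chigh cells at day 2 were led by monocyte genes, with 11 of 14 lower in Ly6Clow cells (median -3.14, percentile 0). MHC class II genes had 8 of 10 lower (median -1.94), among them Ciita, the master regulator of the class, at 12.6-fold and H2-Aa at 5.94-fold. Interferon response genes had 17 of 22 lower (median -1.29), with Isg20 5.04-fold and Isg15 3.67-fold lower. NF-kB target genes had 11 of 20 lower (median -1.03), cAMP and CREB target genes 10 of 16 (median -1.22), immediate early genes 9 of 23 (median -0.75) and cytokine genes 7 of 19 (median -0.86). Cholesterol biosynthesis genes had 6 of 23 lower (median -0.71), and glycolysis and hypoxia genes had 4 of 22 lower (median -0.41, percentile 1.33). Several marker lists of other cells also lay outside the range of random lists at this day. Lower in Ly6Clow cells were fibroblast markers (3 of 11 called, median -0.31, percentile 0.73), endothelial markers (3 of 7, median -0.80, percentile 0.02), T and NK cell markers (0 of 12, median -0.23, percentile 1.97) and erythroid and platelet markers (median -0.50, percentile 1.09), where 1 of 6 genes was called higher. The 3 measured B cell genes had a median of 0.84 at percentile 98.2, with 1 called higher and 1 lower. Dendritic cell (median -0.30), neutrophil (-0.06), skeletal muscle (0.16) and eosinophil and mast cell markers (0.24) lay within the range.

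Genes of lipid mediators were divided between the subsets at day 2. Ptgs2, the inducible cyclooxygenase, was 3.21-fold lower in Ly6Clow cells, while Hpgds, which makes prostaglandin D2, was 3.04-fold and Tbxas1, thromboxane synthase, 2.22-fold higher. Ltc4s, leukotriene C4 synthase, was 3.90-fold higher. Of 12 lipid mediator receptor genes 5 were lower and 0 higher (median -0.94, percentile 0), among them the leukotriene B4 receptor Ltb4r1 at 8.08-fold, the formyl peptide receptor Fpr2 at 6.10-fold and Gpr132 at 5.96-fold. The prostaglandin list had a median of 0.54 at percentile 99.8. The lipoxygenase list had a median of -0.03 and a mean of 0.25, and the arachidonate list a median of 0.23, both within the range of random lists. Ptgs1 (log2 ratio 0.97), Alox5 (0.59), Alox15 (0.84) and Gpr18, a receptor reported to bind RvD2 (-0.95), were under 2-fold on the muscle scale. That scale compresses differences of genes with low values. The day 2 log2 levels in Ly6Chigh and Ly6Clow cells were 5.22 and 6.37 for Ptgs1 and 3.52 and 4.83 for Alox15. For Gpr18 they were 3.60 and 0.54. Alox15 and Gpr18 were under the limit of 50 normalised counts in both subsets.

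The same question was asked at day 4, late in the transition. Ly6Clow cells again had higher transcripts of mature macrophages, engulfment and lysosomes. Npl was 8.66-fold higher, the iron exporter gene Slc40a1 7.34-fold, Mfge8 6.94-fold, the platelet-derived growth factor gene Pdgfc 6.63-fold and the scavenger receptor gene Cd163 4.73-fold. Ly6Chigh cells had higher transcripts of monocytes, MHC class II and lipid mediator receptors, and also of fibroblast, T and NK cell, dendritic cell and endothelial markers. Of 11764 genes 848 were called, 351 higher and 497 lower in Ly6Clow cells.

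The largest ratios toward Ly6Clow cells at day 4 also included Serpinb6a (7.23-fold), Adcy3 (6.27-fold), Pf4 (5.62-fold) and Sel1l3 (5.04-fold). Toward Ly6Chigh cells they were Ly6c2 (114-fold) and Ly6c1 (61.5-fold), which belong to the gate, then Spib (31.4-fold), Siglech (21.6-fold), Hp (20.2-fold), Ccr9 (20.1-fold), Cd7 (19.1-fold) and Fbn1 (19.0-fold). Spib, Siglech and Ccr9 are known from plasmacytoid dendritic cells, and Fbn1 encodes a matrix protein made by fibroblasts.

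In Ly6Clow cells at day 4 mature macrophage genes had 8 of 16 higher and 0 lower (median 1.02), with Lyve1 9.48-fold and Folr2 4.84-fold higher. Repair-associated genes had 8 of 19 higher and 1 lower (median 0.70), with Igf1 3.34-fold higher and Chi3l3 4.10-fold lower. Cell cycle genes had 8 of 35 higher (median 0.63), phagocytosis genes 6 of 20 higher and 1 lower (median 0.59), lysosome genes 5 of 24 (median 0.57) and iron and heme genes 4 of 18 (median 0.57). Cholesterol efflux genes had 4 of 22 higher (median 0.21), with Apoe 2.19-fold and Abca1 2.07-fold higher. Matrix and protease genes had 4 of 22 higher and 3 lower (median 0.43), with Mmp12 3.49-fold higher and the collagen crosslinking gene Lox 6.97-fold lower. Lower in Ly6Clow cells were 11 of 14 monocyte genes (median -2.81), 6 of 10 MHC class II genes (median -1.34), 4 of 16 cAMP and CREB target genes (median -0.49), 3 of 19 cytokine genes (median -0.45), 2 of 20 NF-kB target genes (median -0.38), 2 of 23 immediate early genes (median -0.35) and 1 of 22 interferon response genes (median -0.53). H2-Eb1 was 3.17-fold, Il6 4.15-fold and Il1b 3.48-fold lower. Oxidative phosphorylation (0 of 26 called, median 0.13), cholesterol biosynthesis (1 of 23 lower, median -0.11) and glycolysis genes (1 of 22 lower, median 0.01, mean -0.10) lay within the range of random lists.

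Lipid mediator genes at day 4 included Ptgs1, the constitutive cyclooxygenase, at 2.80-fold and Ltc4s at 2.46-fold higher in Ly6Clow cells. Of 12 receptor genes 4 were lower (median -0.88, percentile 0), namely Ltb4r1 (5.67-fold), Gpr18 (3.65-fold), Gpr132 (2.86-fold) and Fpr2 (2.27-fold). The prostaglandin list had 1 of 10 genes higher (median 0.62), the arachidonate list 0 of 10 called (median 0.40) and the lipoxygenase list 1 of 10 higher (median 0.09, within the range of random lists). Ptgs2 (log2 ratio -0.65), Alox5 (0.45) and Alox15 (-0.76) were under 2-fold on the muscle scale. Alox15 was under the limit of 50 normalised counts in both subsets at day 4. Its log2 levels were 5.27 in Ly6Chigh and 4.23 in Ly6Clow cells, so its ratio was compressed.

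Markers of other cells moved with the Ly6Chigh side at day 4. All 11 fibroblast genes were lower in Ly6Clow cells (median -3.25), with Col3a1 17.6-fold and Col1a1 13.6-fold lower. T and NK cell genes had 8 of 12 lower (median -2.73), with Il2rb 14.8-fold lower and Cd8a listed at 0 in Ly6Clow cells. Dendritic cell genes had 6 of 11 lower (median -1.61), with Flt3 11.6-fold lower, and endothelial genes 5 of 7 (median -1.65). The Ly6Clow side was the higher for skeletal muscle genes (2 of 11, median 0.88). The medians for neutrophil (-0.17), B cell (-0.28), eosinophil and mast cell (-0.04) and erythroid and platelet genes (0.17) lay within the range of random lists. Rescaling to equal totals moved the median gene by -0.10 in this comparison and left 32.0% of calls higher against 41.4% as deposited.

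Across days the subset ratios overlapped. Of 10990 genes eligible at both days, 224 were higher in Ly6Clow cells at both, against 16.8 for independent calls, and 199 were lower at both, against 13.7. Calls of opposite direction numbered 2 and 0. The ratios correlated across genes with Pearson r = 0.758, where genes are not independent replicates.

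**Figure D1:**
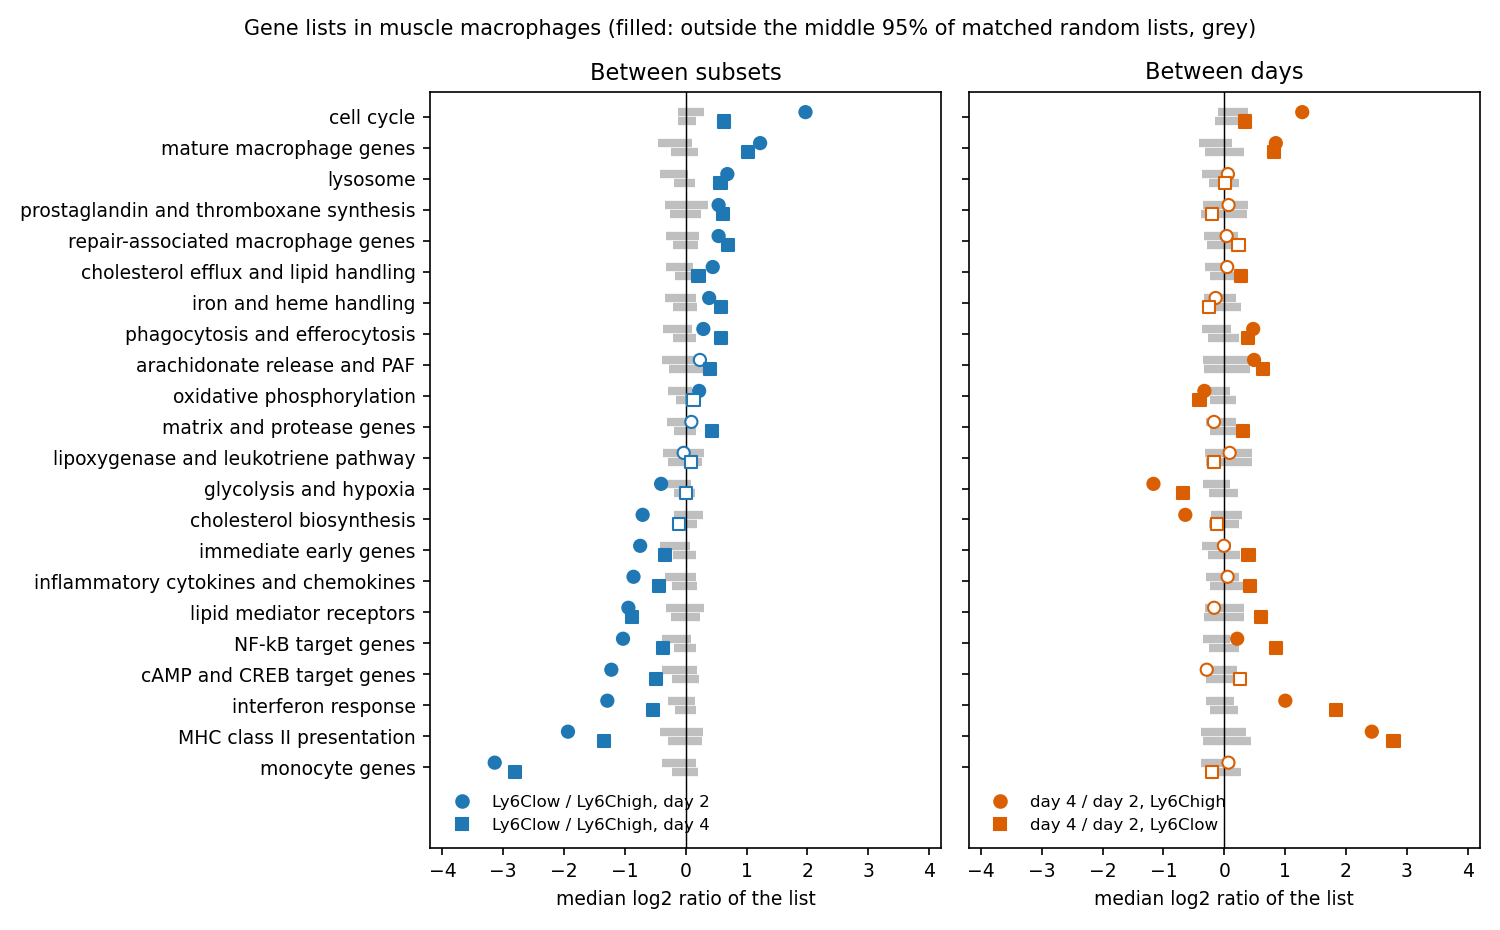
Median log2 ratio (x axis) of each pathway list in muscle macrophages, between subsets on the left (Ly6Clow over Ly6Chigh, circles day 2, squares day 4) and between days on the right (day 4 over day 2, circles Ly6Chigh, squares Ly6Clow). Grey bars span the middle 95% of matched random lists and filled symbols lie outside it, from -3.14 for monocyte genes between subsets at day 2 to 2.78 for MHC class II genes between days in Ly6Clow cells.

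The second question was how each subset differed between day 2 and day 4. Ly6Chigh cells at day 4 had higher MHC class II, interferon response, cell cycle and mature macrophage transcripts and lower glycolysis and cholesterol synthesis transcripts than at day 2. Arg1 (arginase) was 18.4-fold lower at day 4, Ccl5 22.3-fold and Cxcl9 22.2-fold higher. The largest ratios among named genes belonged to matrix genes of fibroblasts. Postn (periostin) was 168-fold, Col1a1 91.9-fold, Col1a2 78.6-fold and Col3a1 71.9-fold higher at day 4. Of 11618 genes 1558 were called, 1123 higher and 435 lower.

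The other largest ratios upward in Ly6Chigh cells were H19 (77.8-fold), an imprinted RNA of growing tissue, Bgn (54.3-fold), Col5a1 (52.6-fold) and Col5a2 (48.6-fold). Downward they were Arg1, Ppbp (17.6-fold), Vcan (11.4-fold), Cgnl1 (11.2-fold), Dmkn (8.70-fold), Pdpn (8.25-fold), Agpat9 (7.05-fold) and Plcb1 (6.89-fold). Of the gate's genes, Ly6c2 was 3.16-fold and Ly6c1 3.29-fold higher at day 4, and Emr1 was 1.65-fold higher.

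All 10 MHC class II genes were higher in Ly6Chigh cells at day 4 (median 2.43), with H2-Eb1 9.02-fold and Ciita 6.18-fold higher. Dendritic cell markers, which share antigen presentation, were higher as well, 9 of 11 (median 2.12), with Siglech 26.8-fold and Flt3 8.08-fold higher. Interferon response genes had 11 of 22 higher (median 1.00), with Ifi44 14.2-fold, and cell cycle genes 17 of 35 (median 1.28), with Top2a 6.06-fold. Mature macrophage genes had 7 of 16 higher (median 0.85), with C1qa 4.30-fold, and phagocytosis genes 7 of 20 higher and 1 lower (median 0.48), with Axl, a receptor for dying cells, 7.05-fold. NF-kB target genes had 3 of 20 higher (median 0.21), a set that includes Cd40 (3.11-fold) and Irf1 (3.00-fold). Glycolysis and hypoxia genes had 14 of 22 lower and 0 higher (median -1.16), with Egln3 6.76-fold, Pgk1 3.25-fold and the glucose transporter Slc2a1 3.13-fold lower. Cholesterol biosynthesis genes had 6 of 23 lower (median -0.64), with Sqle 3.56-fold, and oxidative phosphorylation genes 0 of 26 called (median -0.33, percentile 1.07).

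The lists in this paragraph had medians within the range of random lists between the days in Ly6Chigh cells. Cytokines had 5 of 19 higher and 5 lower, with Cxcl3 4.48-fold and Cxcl2 3.73-fold lower, and repair-associated genes had 4 higher and 6 lower, with Pdgfb 9.90-fold and Igf1 4.66-fold higher. Matrix and protease genes had 5 of 22 higher and 9 lower, with Mmp2 16.6-fold higher and Fn1 (fibronectin) 6.69-fold lower. Cholesterol efflux genes had 6 of 22 higher and 0 lower (median 0.05), with Pltp 8.81-fold and Abcg1 3.36-fold higher, and cAMP and CREB target genes had 3 of 16 lower and 0 higher (median -0.29), with Areg 4.27-fold lower. Monocyte genes had 3 of 14 higher and 6 lower (median 0.07, mean -0.44), lysosome genes 3 of 24 higher and 1 lower (median 0.06), iron and heme genes 2 of 18 higher and 1 lower (median -0.14) and immediate early genes 1 of 23 higher and 2 lower (median -0.01, mean 0.05).

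Hpgd, which breaks down prostaglandins, was 7.78-fold higher in Ly6Chigh cells at day 4, Gpr18 6.73-fold, Ggt5 4.35-fold, Ltc4s 3.38-fold, Ptgs1 3.30-fold and Lpcat2, an enzyme of PAF synthesis, 3.11-fold. Ltb4r1 was 4.62-fold and Ptgs2 2.55-fold lower. The arachidonate list had 2 of 10 higher (median 0.49, percentile 98.9), and the prostaglandin (0.07), lipoxygenase (0.09) and receptor lists (median -0.17, mean 0.01) lay within the range of random lists. Alox5 was at 6.91 at day 2 and 6.74 at day 4 on the log2 scale, and Alox15 at 3.52 and 5.27.

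Markers of other cells were higher in Ly6Chigh cells at day 4 beside each of these groups. All 11 fibroblast genes were higher (median 4.68), 9 of 12 T and NK cell genes (median 3.06), 4 of 11 skeletal muscle genes (median 2.21), 3 of 3 B cell genes (median 1.91) and 4 of 7 endothelial genes (median 1.01). At day 4 Col1a1 was at a log2 level of 12.85, Col3a1 at 12.89 and Postn at 11.26. Neutrophil genes had 1 of 14 higher and 3 lower (median -0.13), and with eosinophil and mast cell (1 of 3 higher, median 1.08) and erythroid and platelet genes (2 of 6 lower, median -0.08) they lay within the range of random lists.

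Ly6Clow cells at day 4 had higher interferon response, MHC class II and NF-kB target transcripts than at day 2 and lower glycolysis transcripts. H19 was 98.1-fold, Ciita 46.7-fold, Dnase1l3 43.8-fold, Lag3 37.2-fold, Cd4 36.7-fold, Serpina3g 28.1-fold, Ifi44 24.0-fold and Tlr12 23.4-fold higher. Arg1 was 17.0-fold, Fn1 9.73-fold, Ppbp 8.70-fold, Mmp8 5.16-fold, Slpi 4.97-fold, Cgnl1 4.94-fold, Chi3l3 4.90-fold and Jag1 4.87-fold lower. Of 11560 genes 1309 were called, 934 higher and 375 lower.

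Interferon response genes had 21 of 22 higher in Ly6Clow cells at day 4 (median 1.84), with Ifit2 11.2-fold and Gbp2 11.1-fold, and the interferon-induced chemokine genes Cxcl9 and Cxcl10 were 21.3-fold and 14.3-fold higher. MHC class II genes had 8 of 10 higher (median 2.78), with H2-Aa 15.1-fold. NF-kB target genes had 9 of 20 (median 0.85), cytokines 6 of 19 with 1 lower (median 0.42), mature macrophage genes 7 of 16 (median 0.82), immediate early genes 3 of 23 (median 0.40) and phagocytosis genes 5 of 20 with 2 lower (median 0.39). Axl was 14.2-fold higher, and so were Slc40a1 (15.4-fold) and Spic (10.4-fold), a transcription factor of heme-handling macrophages. Cell cycle genes were split, with 5 of 35 higher, such as Ccnb2 (2.90-fold), and 4 lower, such as the replication gene Mcm2 (2.93-fold), around a median of 0.34. Glycolysis genes had 5 of 22 lower (median -0.68), with Pkm 2.84-fold, and oxidative phosphorylation genes 1 of 26 (median -0.41).

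Cholesterol efflux genes in Ly6Clow cells had 5 of 22 higher and 4 lower at day 4 (median 0.27), with Pltp 9.77-fold higher and Cd36 3.63-fold lower. Matrix genes had 4 higher and 6 lower of 22 (median 0.31, mean -0.05). Within the range of random lists were repair-associated genes (5 of 19 higher, 3 lower, median 0.23), monocyte genes (4 of 14 higher, 3 lower, median -0.21) and lysosome genes (0 of 24 called, median 0.01, mean -0.01). So were cholesterol biosynthesis genes (2 of 23 lower, median -0.12), cAMP and CREB target genes (2 of 16 higher, 1 lower, median 0.26) and iron and heme genes (2 of 18 higher, 2 lower, median -0.25, mean 0.10). Skeletal muscle markers were higher at day 4 in 9 of 11 genes (median 2.68), with Mylpf, a myosin light chain, 20.0-fold, fibroblast markers in 5 of 11 (median 2.21), with Col1a1 15.1-fold, and dendritic cell markers in 2 of 11 (median 1.08). Neutrophil markers had 5 of 14 lower and 0 higher (median -0.19, percentile 2.35), and 2 of 3 B cell genes were higher (median 1.16, percentile 98.97). T and NK cell (1 of 12 higher, median 0.27), endothelial (0.09), eosinophil and mast cell (0.48) and erythroid and platelet genes (2 of 6 lower, median 0.69) lay within the range of random lists.

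Among lipid mediator genes Hpgd was 15.04-fold, Ggt5 9.99-fold, Lpcat2 6.92-fold and Ptgs1 4.72-fold higher in Ly6Clow cells at day 4. The arachidonate list had 3 of 10 higher (median 0.63) and the receptor list 3 of 12 with 1 lower (median 0.61, percentile 99.9), with Ptger4, a prostaglandin E2 receptor, higher by a log2 ratio of 1.32, and Ltb4r1 3.24-fold lower. The prostaglandin (median -0.20, mean 0.40) and lipoxygenase lists (median -0.17, mean 0.36) lay within the range of random lists. Ptgs2 (log2 ratio -0.32), Alox5 (-0.30), Alox15 (-0.42) and Gpr18 (1.83, at levels under the limit of 50) were not called.

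Between the subsets 546 genes were higher at day 4 in both, against 66.8 for independent calls among 11129 eligible genes, and 203 were lower in both, against 12.7. Calls of opposite direction numbered 2 and 1. The day ratios of the subsets correlated across genes with Pearson r = 0.800, where genes are not independent replicates.

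The third question was whether the subset difference itself differed between the days, taken as the subset ratio at day 4 minus that at day 2. Of 12047 genes 749 differed at least 2-fold in this way, 263 with the ratio shifted toward Ly6Clow cells and 486 toward Ly6Chigh cells. Cell cycle genes shifted toward Ly6Chigh cells in 21 of 35 genes and toward Ly6Clow cells in 1 (median -1.24), with Top2a at -2.40 and Rrm2 at -2.32. Interferon response genes shifted toward Ly6Clow cells in 9 of 22 (median 0.88), with Oas2 at 1.56, and MHC class II genes in 2 of 10 with 1 the other way (median 0.76), with Ciita at 2.92. Cytokines shifted toward Ly6Clow cells in 5 of 19 and the other way in 1 (median 0.49), with Cxcl10 at 2.05, Il1b at 1.71 and Il6 at -1.48. Ptgs2 shifted by 1.03 and Fpr2 by 1.42.

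Other lists above the range of random lists in this shift were NF-kB target genes (2 of 20 toward Ly6Clow cells, median 0.60), immediate early genes (2 of 23, median 0.59), cholesterol biosynthesis genes (1 of 23, median 0.52), monocyte genes (4 of 14 and 3 the other way, median 0.50), cAMP and CREB target genes (2 of 16, median 0.48) and lipid mediator receptors (2 of 12, median 0.30). Below the range, with small medians, were repair-associated genes, which were split (4 of 19 toward Ly6Clow cells and 3 the other way, median -0.22, mean 0.05), cholesterol efflux genes (1 and 2 of 22, median -0.18) and mature macrophage genes (0 of 16 called, median -0.17, mean 0.02). So were phagocytosis genes (1 and 0 of 20, median -0.13), oxidative phosphorylation genes (0 of 26, median -0.09) and lysosome genes (0 and 1 of 24, median -0.06). Glycolysis (median 0.28), matrix (0.20), iron and heme (0.09), arachidonate (0.03), lipoxygenase (-0.08) and prostaglandin genes (median -0.17, mean 0.01) lay within the range, as did neutrophil (-0.20) and eosinophil and mast cell markers (-0.28).

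The largest shifts toward Ly6Clow cells were those of Clec4n (3.46), Ciita, Emr4 (2.82), Itgal (2.65), Vcan (2.56), Pilrb2 (2.55), Dmkn (2.46) and Ear2 (2.29). Toward Ly6Chigh cells they were Spib (-4.11), Ccr9 (-3.86), Cilp (-3.40), Siglech (-3.35), Col5a2 (-3.31), Il2rb (-3.28), Col6a3 (-3.24) and Postn (-3.18). Fibroblast markers shifted that way in 11 of 11 genes (median -2.51), T and NK cell markers in 8 of 12 (median -2.42), dendritic cell markers in 6 of 11 (median -1.36) and endothelial markers in 2 of 7 (percentile 0.08). B cell markers had 1 of 3 each way (median -0.72, percentile 0.67). Skeletal muscle (1 of 11, median 0.62) and erythroid and platelet markers (1 of 6, median 0.68) shifted toward Ly6Clow cells. With equal totals 24.6% of the calls were toward Ly6Clow cells, against 35.1% as deposited.

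Neutrophils at day 1 were compared with Ly6Chigh macrophages at day 2, the earliest macrophages analysed here, so that cell type and day differed together. Neutrophils had higher transcripts of their granule and alarmin genes, of chemokines and of the enzymes that start leukotriene and prostaglandin synthesis. S100a9 was 1631-fold and S100a8 1024-fold higher. Ptgs1 was 113-fold, Alox5, the lipoxygenase of leukotriene synthesis, 39.8-fold and Ptgs2 17.43-fold higher. Macrophages had higher transcripts of the mature macrophage, phagocytosis and MHC class II lists. Of 11789 genes 6890 were called, 3638 higher and 3252 lower in neutrophils.

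Because the neutrophil values sum to 26.0 M normalised counts, equal totals moved the median gene by -1.01 and left 21.8% of calls higher against 52.8% as deposited. No called gene named here turned its direction, and no direction is given for a list whose median lay between 0 and that shift. G0s2 (974-fold), Il1f9 (966-fold), Cxcr2 (815-fold), Asprv1 (598-fold), Chi3l1 (562-fold) and Irg1 (522-fold) were the next largest toward neutrophils. Among the largest toward macrophages were the mannose receptor gene Mrc1 (96.4-fold), Ms4a6c (66.4-fold), Plxnb2 (60.9-fold), Pld4 (60.8-fold), Vcan (57.6-fold), Ms4a6b (57.3-fold) and F13a1 (57.1-fold). Ly6g was at a log2 level of 7.20 in neutrophils and listed at 0 in macrophages, and Emr1 was 4.00-fold lower in neutrophils.

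All 14 measured neutrophil markers were higher in neutrophils (median 7.30, and 6.49 with equal totals). NF-kB target genes had 18 of 20 higher and 1 lower (median 2.73, then 1.68), with Icam1 24.9-fold higher. Cytokines had 13 of 19 higher and 2 lower (median 2.34, then 1.50), with Il1a 148-fold, Ccl3 38.8-fold and Cxcl2 35.7-fold higher, and immediate early genes 17 of 23 with 2 lower (median 2.06, then 1.01), with Egr3 197-fold higher. The lipoxygenase list had 5 of 10 higher and 1 lower (median 1.57, then 0.64), with Ggt5 30.7-fold and Cyp4f18 16.7-fold higher. Iron and heme genes (10 of 18 higher, 4 lower, median 1.43, then 0.38) and cAMP and CREB target genes (10 of 16 higher, 3 lower, median 1.44, then 0.39) also lay above random lists. The 3 measured eosinophil and mast cell genes were higher (median 2.17, within the range of random lists), with Siglec5, a marker of eosinophils, 288-fold higher. Mmp9, a granule protease, was 448-fold higher.

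Mature macrophage genes had 12 of 16 lower in neutrophils and 1 higher (median -4.23), with C1qb 48.6-fold and the engulfment receptor gene Mertk 38.2-fold lower. Phagocytosis genes had 15 of 20 lower and 3 higher (median -3.33), MHC class II genes 7 of 10 lower (median -2.73), repair-associated genes 13 of 19 lower and 5 higher (median -2.56), with Pparg 30.0-fold and Trem2 28.7-fold lower, and cholesterol efflux genes 12 of 22 lower and 4 higher (median -2.03). Monocyte genes had 9 of 14 lower and 4 higher (median -1.81), matrix genes 11 of 22 lower and 6 higher (median -1.55) and oxidative phosphorylation genes 14 of 26 lower (median -1.05). Of the receptors Fpr1 was 63.0-fold, Fpr2 23.9-fold and the PAF receptor Ptafr 5.67-fold higher, and Cmklr1, a chemerin receptor, 15.5-fold lower. Hpgd was 5.48-fold lower. Alox15 (log2 ratio -0.37) and Gpr18 (-0.77) were not called, at log2 levels of 2.71 and 1.57 in neutrophils.

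**Figure D2:**
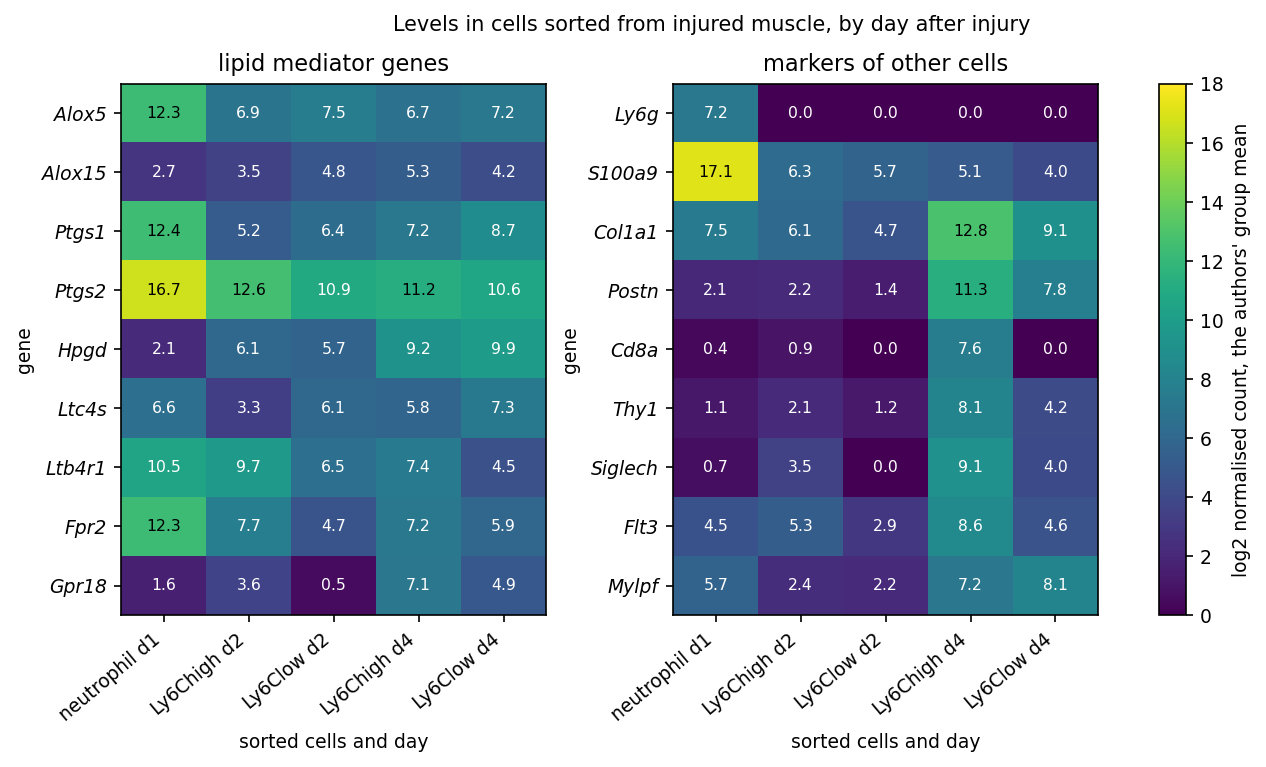
Level of 9 lipid mediator genes (left) and 9 markers of other cells (right) in each sorted group, printed in the cells and coloured as log2 normalised count, the authors' group mean, with d1, d2 and d4 for days 1, 2 and 4 after injury. Alox5, Ptgs1 and Ptgs2 were highest in neutrophils at 12.34, 12.38 and 16.72, and Col1a1 was highest in Ly6Chigh cells at day 4 at 12.85.

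The last question was what RvD2 did to gene expression in cultured macrophages. With RvD2 9 of 13 tested target genes of cAMP signalling and 7 of 23 immediate early genes rose, and 16 of 35 cell cycle and 4 of 23 cholesterol biosynthesis genes fell. As lists, by limma camera, the cAMP targets passed with an estimated correlation (adjusted p = 0.0406, median 0.90), and the others passed with the preset correlation but not with the estimated one, at adjusted p = 0.0905 for immediate early genes and 0.531 for each of the others. The largest rise among named genes was in Cytip, a regulator of integrin adhesion, from a log2 level of 9.40 ± 0.34 to 11.14 ± 0.43 (SD, n = 3 each), which is 3.34-fold. The nuclear receptor genes Nr4a1 and Nr4a2 rose 2.63-fold and 2.47-fold, and Vegfa, which encodes a growth factor for vessels, rose 1.94-fold. Ccnb2, a mitotic cyclin, fell by 0.98 on the log2 scale from 8.25 ± 0.06 to 7.27 ± 0.06. The cyclooxygenase and lipoxygenase genes were not among the genes that passed the test.

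limma called 282 of 15243 genes at an adjusted p under 0.05, 120 higher and 162 lower with RvD2, of which 115 changed at least 1.5-fold and 26 at least 2-fold. In all 282 the 3 RvD2 libraries lay beyond the 3 controls, as they did in 3195 tested genes (20.96%, where chance gives 10%). Leaving out control 1, 2 or 3 lowered the count to 122, 106 and 140, leaving out RvD2 library 2 or 3 lowered it to 89 and 79, no filter gave 137 and limma without the trend 49. Of 45 called genes that the rule for named genes took up, 22 were called in each of the 6 fits without 1 library, and all 45 kept their sign.

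Other large rises with RvD2 were Tlr5, the flagellin receptor (3.23-fold, limma adjusted p = 0.00587), Arrdc3 (3.14-fold), Chac1 (log2 change 1.32), Trib3 (2.42-fold, limma adjusted p = 0.00282) and Cnnm2 (2.35-fold). Chac1 and Trib3 are known targets of the stress factor Atf4. Other large falls were those of Ddit4l, which fell by 1.20 on the log2 scale, the helicase gene Pif1 by 1.14, the spindle gene Troap by 1.02, the lipoprotein receptor gene Lrp8 by 0.99, Gdf15 by 0.96 and Ckap2 by 0.90. Ccnb2 and Lrp8 had limma adjusted p-values of 0.00282 each. Cytip lies on chromosome 2 from 58129137 to 58195532 (ENSMUSG00000026832) and Ccnb2 on chromosome 9 from 70407692 to 70421547 (ENSMUSG00000032218). Without RvD2 library 2 Chac1 was not called, without control 1 Pif1 was not, and without RvD2 library 3 Gdf15 was not, while Troap was called in 1 of the 6 fits without 1 library.

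In the cAMP and CREB list 9 of 13 tested genes rose, and 11 when adjusted over the list alone (median 0.90, limma camera adjusted p = 2.11e-15, and adjusted p = 0.0406 with an estimated correlation). Besides Nr4a2 and Vegfa they included the phosphodiesterase genes Pde3b (log2 change 1.19) and Pde4b (1.21), whose products break down cAMP. Pde4b was called in 1 of the 6 fits without 1 library. Immediate early genes rose in 7 of 23, and 12 when adjusted over the list alone (median 0.32, limma camera adjusted p = 2.51e-10, but adjusted p = 0.0905 with an estimated correlation), with Fos at 1.08, Fosl2 at 0.68 and Zfp36 at 0.62. Glycolysis and hypoxia genes rose in 4 of 23, and 10 when adjusted over the list alone (median 0.13, limma camera adjusted p = 3.36e-08, but adjusted p = 0.0905 with an estimated correlation), namely Egln3 (0.86), the glucose transporter Slc2a1 (0.71), the hexokinase Hk2 (0.51) and Ero1l (0.38). Of these, Slc2a1, Hk2 and Fosl2 were called in all 6 fits without 1 library, Fos in 4, Egln3 in 3, Ero1l in 2 and Zfp36 in 1.

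Cell cycle genes fell in 16 of 35, and in 21 with 1 rise when adjusted over the list alone (median -0.42, limma camera adjusted p = 1.69e-15, but adjusted p = 0.531 with an estimated correlation). Cdc20 fell by 0.87 on the log2 scale, Ccnb1 by 0.85 and the kinetochore motor Cenpe by 0.82, and each was called in all 6 fits without 1 library. Cholesterol biosynthesis genes fell in 4 of 23, and 16 when adjusted over the list alone (median -0.39, limma camera adjusted p = 7.79e-12, but adjusted p = 0.531 with an estimated correlation). Lss, lanosterol synthase, fell by 0.72 and was called in all 6 fits without 1 library. Iron and heme genes fell in 2 of 18, and 4 when adjusted over the list alone (median -0.11, limma camera adjusted p = 0.000704, but adjusted p = 0.531 with an estimated correlation), namely the iron exporter Slc40a1 by 0.69 and Txnrd1 by 0.55, which were called in 6 and 3 of the 6 fits without 1 library.

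NF-kB target genes rose in 3 of 20, and 7 when adjusted over the list alone (median 0.21, limma camera adjusted p = 1.20e-06, but adjusted p = 0.531 with an estimated correlation). They were Cd83 (1.05), Nfkbie (0.69) and Nfkb2 (0.43), of which Nfkbie and Nfkb2 were called in 0 of the 6 fits without 1 library. Cytokines had 2 rises and 1 fall among 14, and 3 rises and 1 fall when adjusted over the list alone (median 0.38, limma camera adjusted p = 0.0344, but adjusted p = 0.629 with an estimated correlation). Osm, oncostatin M, rose by 0.99 and the inflammasome gene Nlrp3 by 0.52, while the chemokine gene Ccl3 fell by 0.79. The cytokine list did not pass camera in 4 of the 6 fits without 1 library, with either other filter or without the trend. Nlrp3 was called in 1 of the 6 fits without 1 library, and Osm and Cd83 were not called without RvD2 library 3. The interferon list had a median of 0.49 (limma camera adjusted p = 2.40e-05, but adjusted p = 0.629 with an estimated correlation), with 0 of 22 genes called by limma over all genes or over the list alone. Across all genes limma gave 2371 at an unadjusted p under 0.05.

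Few lipid mediator genes passed the test in BMDM. Hpgds fell by 0.42 on the log2 scale and Ptafr, the receptor for PAF, by 0.49, and each was called in 1 of the 6 fits without 1 library. Ptgs2 was at 10.48 ± 0.40 without and 10.63 ± 0.39 with RvD2 (SD, n = 3 each), a change of 0.15 within the spread (limma adjusted p = 0.817). Ptgs1 differed by 0.02 (limma adjusted p = 0.954) and Alox5 by -0.55 (SE 0.51, limma adjusted p = 0.685). Alox15 (0.17 and 0) and Gpr18 (0.64 and 0.24, mean log2 levels without and with RvD2) were under the filter. Ptgs2 lies on chromosome 1 from 150100031 to 150108227 (ENSMUSG00000032487), Alox5 on chromosome 6 from 116410077 to 116461178 (ENSMUSG00000025701) and Gpr18 on chromosome 14 from 121911253 to 121915781 (ENSMUSG00000050350). By limma camera the lists did not pass, with adjusted p = 0.148 for receptors (median -0.10, 1 of 12 fell), 0.839 for prostaglandin synthesis (median 0.04, 1 of 11 fell), 0.986 for the lipoxygenase pathway (0 of 8, median 0.04, mean -0.09, direction up) and 0.742 for arachidonate release (0 of 10, median -0.00, mean 0.02, direction up).

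The other pathway lists did not pass with RvD2 either. The limma camera adjusted p was 0.246 for repair-associated genes (median 0.07, 1 rise and 1 fall of 17), 0.148 for monocyte genes (median 0.13), where Thbs1 rose by 0.52, and 0.135 for mature macrophage genes (median 0.06, 0 of 15, and 1 when adjusted over the list alone). It was 0.156 for MHC class II genes (median 0.10, 0 of 7), 0.940 for phagocytosis genes (median -0.01, mean 0.02), where Cd300lf rose by 0.56, and 0.701 for matrix genes (median 0.02), where Mmp19 rose by 0.46. Thbs1 was called in 3 and Mmp19 in 2 of the 6 fits without 1 library, and Cd300lf was not called without RvD2 library 3. For oxidative phosphorylation (adjusted p = 0.986, 0 of 26), cholesterol efflux (0.742, 0 of 21) and lysosome genes (0.701, 0 of 24) by limma camera the medians were 0.00 each, with a mean of -0.02 for lysosome genes. Some of these calls depend on the fit: mature macrophage genes passed limma camera with the replicate number as a block (adjusted p = 0.00547) and without control 3 or RvD2 library 1, monocyte genes with the filter of 50 and without control 3 or RvD2 library 2, and lysosome and receptor genes without control 1.

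Transcripts used as markers of other cells were present in BMDM libraries of both groups, and which cells they came from was not tested. Col1a1 was at log2 levels of 13.95 to 14.53 across the 6 libraries. S100a9 ranged from 10.31 in control 1 to 12.21 in control 3, and the endothelial gene Cdh5 from 6.87 in RvD2 library 2 to 8.47 in RvD2 library 1. By limma camera the adjusted p was 0.701 for fibroblast (median 0.05), 0.701 for neutrophil (median -0.23) and 0.14995 for endothelial genes (median 0.31). It was 0.313 for B cell (median 0.35), 0.701 for eosinophil and mast cell (median 0.09), 0.156 for dendritic cell (median 0.21) and 0.940 for erythroid and platelet genes (median -0.02), all by limma camera and with 0 genes called. Endothelial genes passed limma camera with the block (adjusted p = 0.0146) and without RvD2 library 2, fibroblast genes without RvD2 library 2 and neutrophil genes without control 1. T and NK cell and skeletal muscle markers had 2 tested genes each and no list test. The control cells are labelled untreated, and whether they received the vehicle of RvD2 is not stated in the labels.

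**Figure D3:**
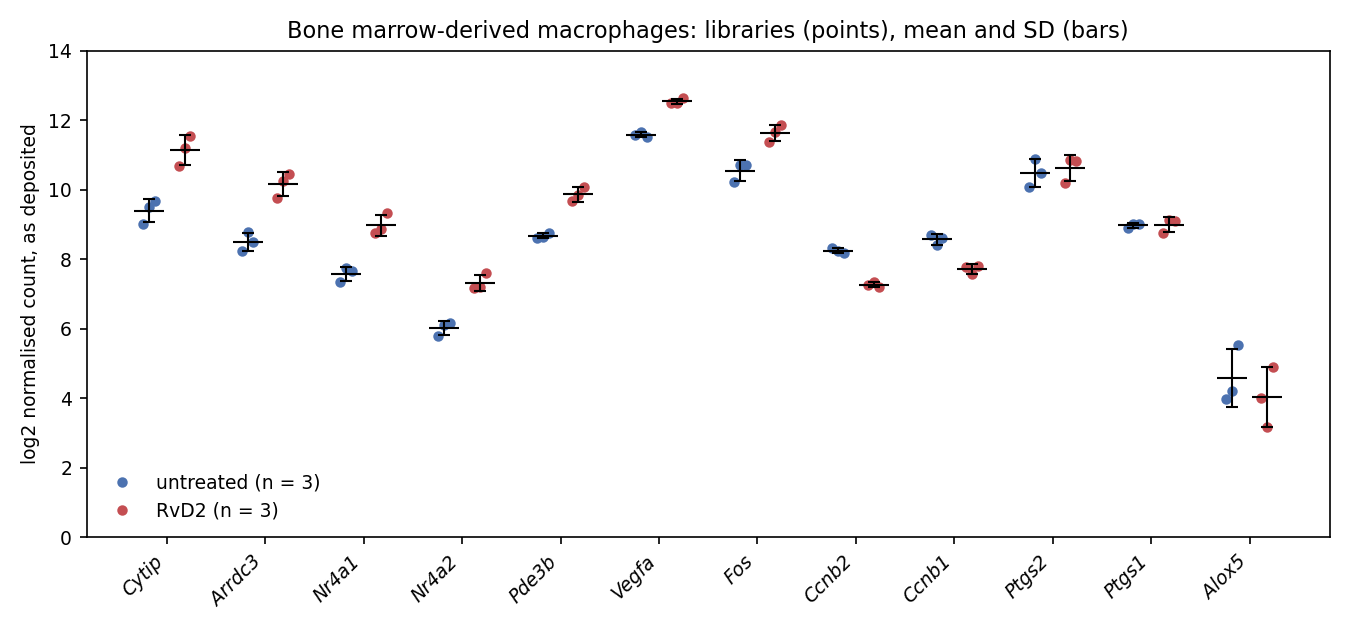
Log2 normalised counts as deposited (y axis) of 12 genes in BMDM without (blue, n = 3) and with RvD2 (red, n = 3), with each library as a point, the mean as a long line and SD as bars. From Cytip to Ccnb1 the 3 RvD2 libraries lie beyond the 3 controls, and for Ptgs2, Ptgs1 and Alox5 the groups overlap.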

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

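The BMDM alternatives with a pseudocount of 1 and with the trend of GC content and length removed were chosen after the result was seen, and the others were planned. In BMDM the 282 genes became 137 with no filter, where more genes were tested, 49 without the trend in limma, 115 with an added 1.5-fold limit and 999 at an unadjusted p under 0.01. Fits without 1 library gave 79 to 288 genes, with fewer samples. The replicate number as a block gave 1064 genes. To look for pairing, each gene's group mean was taken away, and the deviations were correlated across genes between control and RvD2 libraries. Deviations of libraries of the same number correlated by 0.28, 0.01 and 0.04, and those of different number by -0.25 to 0.19. For 3 of 6 libraries the highest of these correlations was with their own number. Some markers of other cells ran in the same order by number in both groups. S100a9 was at 10.31, 10.99 and 12.21 in controls 1 to 3 and at 10.39, 10.82 and 11.46 with RvD2. Cdh5 was at 7.97, 7.26 and 7.49, and at 8.47, 6.87 and 8.23. Others did not, such as Postn (9.53, 9.47 and 9.67, and 9.47, 9.58 and 9.54). The labels do not state a pairing, so whether the numbers pair stays open, and the main fit ignored any pairing. Pseudocounts, the filter of 50, both rescalings and the removal of GC and length trends gave 281 to 389 genes. The gene lists past the threshold were 9 with the preset and 1 with the estimated correlation. Over the alternatives for named BMDM genes, 637 values kept their direction and side of the threshold and 130 kept their direction but lost the threshold. The lists were tested under these alternatives after the result was seen, with the preset correlation of 0.01. Of 144 limma camera values of the 9 lists that passed, 137 passed again in the same direction, and the 7 that did not were all of the cytokine list. Since these fits kept the preset, they do not bear on the loss of lists under the estimated correlation. Lists that had not passed did so in 12 values, 2 of them with the block, where 11 lists passed, and 9 of them in fits without 1 library. The other was monocyte genes with the filter of 50.

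No paired analysis was possible because the muscle table holds group means, and the limma settings, the fits of 2 groups, the block and leaving samples out could not be run there. No filter moved nothing in muscle, since a higher group of 50 already implies it. With a pseudocount of 50 the calls were 830 between subsets at day 2, 552 at day 4, 1033 between days in Ly6Chigh cells and 383 for the shift between days. At 1.5-fold they were 3002, 2208, 3402, 3276 in Ly6Clow cells between days, and 1962 for the shift. At 4-fold they were 254, 234, 442, 261, 3197 for neutrophils, and 165. These follow from the limits, which admit more or fewer genes. For other changes in count the cause was not tested. Of the values of named genes under these settings, 4867 stayed on their side of the 2-fold rule and 141 crossed it. Of the medians of lists outside the range of random lists, 580 moved by less than 0.2 and 146 by more. No called gene among the named genes and none of these lists changed sign, and other genes were not followed for sign. Low genes are limited by values listed at 0, which held for 49.3 to 51.5% of genes in BMDM and 45.9 to 53.0% in muscle. Depth was not tested as the cause, and the BMDM library of highest estimated depth, control 2 (14.3 M gene reads), had the largest share at 0 (51.5%). By the estimated step, 1 read is worth 0.885 normalised counts in control 2, so the floor of 1 sets genes with 1 read to 0 there. In the other BMDM libraries 1 read is worth 1.06 to 1.41 and stays above the floor.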

Other observations

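The tests on fibroblast genes and on the RvD2 gene count were chosen after the results were seen, and the test of RvD2 genes in muscle cells was set before.

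Of 120 genes that RvD2 raised in BMDM 118 were measured in muscle, and as a set they were lower in Ly6Clow than in Ly6Chigh macrophages, with 23 above 0 at day 2 and 29 at day 4 and median log2 ratios of -0.79 and -0.36. Of 162 lowered genes 154 were measured, 99 had a ratio above 0 at day 2 and 107 at day 4, with medians of 0.49 and 0.40. The hypothesis that RvD2 shifts cultured macrophages toward the Ly6Clow program predicted raised genes above random lists at day 2. Instead the raised genes lay at percentile 0 of matched random lists, and the lowered genes at percentile 100. Without the cell cycle list 138 lowered genes were left, also at percentile 100 (median 0.36). That list does not hold every gene of cell division, with the spindle gene Troap outside it. How far the lowered genes follow cell division therefore stays open. The raised genes were not retested without any list. Lists with members raised by RvD2 were themselves lower in Ly6Clow cells at day 2, with medians of -1.22 for cAMP and CREB targets, -1.03 for NF-kB targets and -0.75 for immediate early genes. How far the raised genes follow these lists stays open too. Between day 2 and day 4 the picture differed: in Ly6Clow cells the raised genes lay at percentile 99.96 (median 0.17, 76 of 118 above 0) and the lowered genes at percentile 99.5 (median 0.15), and in Ly6Chigh cells they lay at 55.9 and 99.5. What this may mean for cells in muscle was not tested.

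Fibroblast transcripts were abundant in Ly6Chigh cells at day 4, with Col3a1 at a log2 level of 12.89, Col1a1 at 12.85 and Postn at 11.26, against 8.72, 9.06 and 7.80 in Ly6Clow cells, although the CD45 selection would remove fibroblasts. A lower share of macrophages, raising every other cell type alike, is argued against by skeletal muscle markers, whose median log2 ratio of Ly6Chigh to Ly6Clow cells was -0.79 (10 genes with the higher group at 50 or more) while that of all 11 fibroblast markers was 3.25. These values speak only against a like rise of all cell types. A lower share of macrophages with only some other cell types raised stays open. Of a second list of 22 fibroblast genes, written after that result, 4 were already among the largest ratios, and 14 of the other 18 (77.8%) were at least 2-fold higher in the Ly6Chigh cells, while the remaining 4 were under the level of 50 in both, so whether fibroblasts or their RNA in the gate are the source stays open. Of the 11 markers 9 also passed the filter in BMDM, with Col1a1 at 13.95 or more, and markers with the higher group at 50 or more were also higher in the Ly6Chigh cells for T and NK cells (9 genes, median 3.28), dendritic cells (9 genes, 1.66) and endothelial cells (5 genes, 1.86), where the Results give medians over all measured genes. No biological explanation was tested, and with group means it stays open whether 1 or both samples carried these transcripts.

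For the 282 genes changed in BMDM, the split of the libraries by treatment was the 1 of 10 splits with as many genes, and the highest other split gave 3, but 10 splits are too few for a share under 0.05. A trend with GC content or transcript length is argued against as the whole cause, since 96.1% of the genes were still called after its removal. The authors' scaling is argued against likewise, since at least 96.1% were still called under each of 2 rescalings. A vehicle given with RvD2 stays open, since the labels call the controls untreated, and a response to RvD2 itself is a hypothesis that these libraries cannot separate from it.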
